A study of Mus musculus with 6 samples.

How the data were processed

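The series measured RNA from mouse lung tumours in 2 groups of 3 libraries each, Ctrl and SD. Per the labels, mice spent 20 hours a day, from 14:00 to 10:00, in a home cage or an SD cage during 7 weeks after a virus injection, with lights on from 8:00 to 20:00. The labels do not spell out the letters SD, and the series title speaks of sleep deficiency. The hour at which tissue was taken is not given in the sources used here. The genotype label carries a number that is 1 higher in each sample than in the sample before, while the series' design text names a single genotype; the 6 samples were treated as 1 genotype. Total RNA was extracted with TRIzol and 1.5 ug entered a NEBNext Ultra library kit, per the labels' protocols, which state no strand setting. Without a strand setting, reads from genes that overlap on opposite strands cannot be told apart, and near-identical paralogs can share reads.

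Reads were processed with HISAT2 2.0.5 and featureCounts 1.5.0-p3 on mm10, per the submitters' processing notes, which give no order or settings. The authors deposited 1 table of CPM, a gene's reads scaled to a common library size, for 10191 genes, 1 column per library, per the file headers. Which genes were kept is not stated; 10166 were protein coding in the GENCODE annotation of the same genome build, no value lay below 1 read, and the mitochondrially encoded genes of the lists were not among them. Of the gene IDs, 10190 had a name in the reference annotation. Symbols equalled that name, ignoring case, for 10147, and 20 symbols in the table had been turned into dates or numbers, so the reference names were used.

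In each column the deposited CPM values were multiples of 1 step, which gave library totals of 6511192 to 7417095 reads and let whole reads be recovered for 61022 of 61146 values (99.8%), with a tolerance of 0.01 read. The other 124 values lay in 50 genes, 121 of the values in SD columns and 3 in Ctrl columns. The 50 genes were among the 60 listed first in the table, ahead of Aaas, where a largely alphabetical listing begins. Their values were used as deposited. The listing after the first 60 is not strictly alphabetical. Acta2, Aldh1a1 and Pax5, 2.93-fold, 3.06-fold and 5.75-fold higher in SD, stood ahead of Ace, Ahsa1 and Nr1d2, whose folds were 1.43, 1.67 and 1.02. How the rows were ordered was not tested. A count of 3 reads, taken as the floor, equalled 0.404 to 0.461 CPM, and such floors cover counting error only.

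The design written before the data were examined named a count test for counts, and limma on a log scale if the table held normalized values, which was the case. Genes with at least 1 CPM in at least 3 libraries were tested (10004 genes) with limma's moderated test with trend on log2(CPM + 1), group as the sole term, and Benjamini-Hochberg adjustment with a threshold of 0.05. Fold changes on that scale understate the change of low genes; folds given as such are ratios of mean CPM. Gene lists were also fixed before the data were examined, together with the alternatives and the rule for named genes. The 41 lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. With an estimated correlation, camera also takes its degrees of freedom from the 6 libraries instead of from the genes, which raises p whatever the correlation. Nothing in the labels says that the libraries of a group came from separate animals beyond the words for biological replicate, so p-values measure the spread between these samples.

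Named genes were the 10 largest rises and 10 largest falls in log2 fold change among genes past the threshold whose SD libraries all lay on 1 side of the Ctrl libraries with a mean of at least 1 CPM, leaving out unnamed gene models and antigen receptor segments; the 2 to 4 members with the smallest p of each list described; clock genes; and the Acsl genes. Members that moved against the rest of their list, and Decr1, were named after their values were seen.

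The edgeR quasi-likelihood test and the DESeq2 test ran on the recovered reads, rounded, as alternatives; edgeR called 5612 of 9701 genes. Other alternatives were size factors and upper quartile scaling, other filters and pseudocounts, quantile normalization, TPM, sample weights, limma-voom, the replicate number as a block, each library left out in turn, and a bound of 2-fold. The edgeR test had been foreseen for the case that reads could be recovered, and TMM scaling and the runs without the 50 genes or without the first 60 were chosen after seeing the data. List medians outside the first 60 genes had 95% bootstrap intervals from 10000 resamples of the genes of a list. They measure the spread between genes, not between libraries or animals. The test was also checked on counts simulated for this comparison with 200 changed genes and the common dispersion of the edgeR fit. Among 10000 genes tested, 72 of 100 genes changed 1.5-fold and 94 of 100 changed 2-fold were called, and 9 of 175 calls were unchanged genes. In the data 5667 of 10004 genes changed, far more than in the simulation, so these shares need not carry over. Software was R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.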

Results

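RNA was sequenced from lung tumours of mice kept in home cages (Ctrl, 3 libraries) or SD cages (SD, 3 libraries). The comparison asked how the tumour transcriptome differed between the groups, and the series title names circadian disruption and fatty acid oxidation as its subjects. Library totals, recovered from the deposited CPM values, were 7245473, 7417095 and 7021019 reads in Ctrl and 6511192, 6968966 and 6691554 in SD. Values are means ± s.d. in CPM over 3 libraries per group unless stated otherwise, and adjusted p-values of genes are from limma. Coordinates are those of mm10.

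Between the groups, 5667 of 10004 tested genes changed, 2811 higher and 2856 lower in SD. Among the largest falls were Lpcat1, an enzyme of surfactant lipid synthesis (148 ± 2.36 in Ctrl, 12.5 ± 2.13 in SD, 11.8-fold lower, adjusted p = 4.4e-26), and Slc34a2, the phosphate transporter of type 2 alveolar cells (118 ± 11.7 against 10.1 ± 1.01, 11.7-fold lower, adjusted p = 6.8e-25). Dram1, a lysosomal membrane protein linked to autophagy, fell 7.98-fold from 213 ± 17.8. Cybb, the catalytic subunit of the phagocyte NADPH oxidase, fell 9.12-fold from 28.9 ± 2.54, and Pik3ap1, an adaptor of immune cells, 9.05-fold from 22.0 ± 0.938. Fasn, Kcnj15, Egfl6, Slc26a4 and Ociad2 completed the 10 largest falls. For Slc26a4 and Ociad2 the SD means of 0.897 and 0.586 CPM lay near the floor of 3 reads.

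The largest rises included Nrxn2, a synaptic adhesion protein (15.6 ± 2.56 in Ctrl, 144 ± 15.3 in SD, 9.28-fold higher, adjusted p = 1.1e-24), and Tgfbr3, a co-receptor for TGF-beta (26.8 ± 3.29 against 202 ± 8.49, 7.54-fold higher, adjusted p = 1.3e-26). Hspa1a, an inducible heat shock protein, rose 7.09-fold from 11.8 ± 1.75, although it is nearly identical to Hspa1b and both can share reads. Drc7 and Rsph1, parts of the motile cilium, rose from 7.86 ± 2.23 to 47.2 ± 2.28 and from 3.088 ± 0.1302 to 21.01 ± 2.504. Gria1, Lrrc36, Kcna2, Hs3st1 and Fgfr4 made up the rest of the 10 largest rises. Of the genes that passed, 776 were higher and 658 lower by at least 2-fold in the fitted log2 change. The groups did not overlap in 60.3% of tested genes, against 10% by chance. Of the variance, 77.0% lay on the first principal component, which separated the groups.

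Clock genes moved in both directions. Nr1d1, the clock repressor REV-ERB alpha (chromosome 11, 98767932 to 98775333), rose 4.82-fold from 99.4 ± 1.46 to 479 ± 17.0 (adjusted p = 2.6e-29). The clock output factors Hlf, Dbp and Tef rose 3.94-fold, 1.96-fold and 1.60-fold, and Ciart, a repressor of the clock, went from 0.959 ± 0.528 to 4.49 ± 1.67. Per1 and Cry1, repressors of the core loop, rose 1.23-fold and 1.34-fold. Bhlhe40 fell 1.74-fold, Arntl, which encodes BMAL1, 1.58-fold, and Per3 1.98-fold. Clock, the partner of BMAL1, stood at 64.0 ± 6.73 in Ctrl and 139 ± 21.8 in SD. It is 1 of the 60 genes listed first in the table, and its recovered SD reads, 1062, 914 and 812, share the factor 2. Those reads are whole, and 16.5% of the genes outside the first 60 shared some factor of 1.1 to 3.0 in SD. The shared factor by itself therefore says little about Clock. Per2 was at 18.7 ± 0.702 and 21.7 ± 2.04, and Nfil3 at 3.12 ± 0.955 and 2.41 ± 0.896. Cry2, Rora, Nr1d2 and Bhlhe41 differed by 0.02 to 0.05 on the log2 scale. None of these 6 passed. The hour of tissue collection is not given in the sources used here, so a difference in hour between the groups is not told apart from the cages for these genes.

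**Figure D1:**
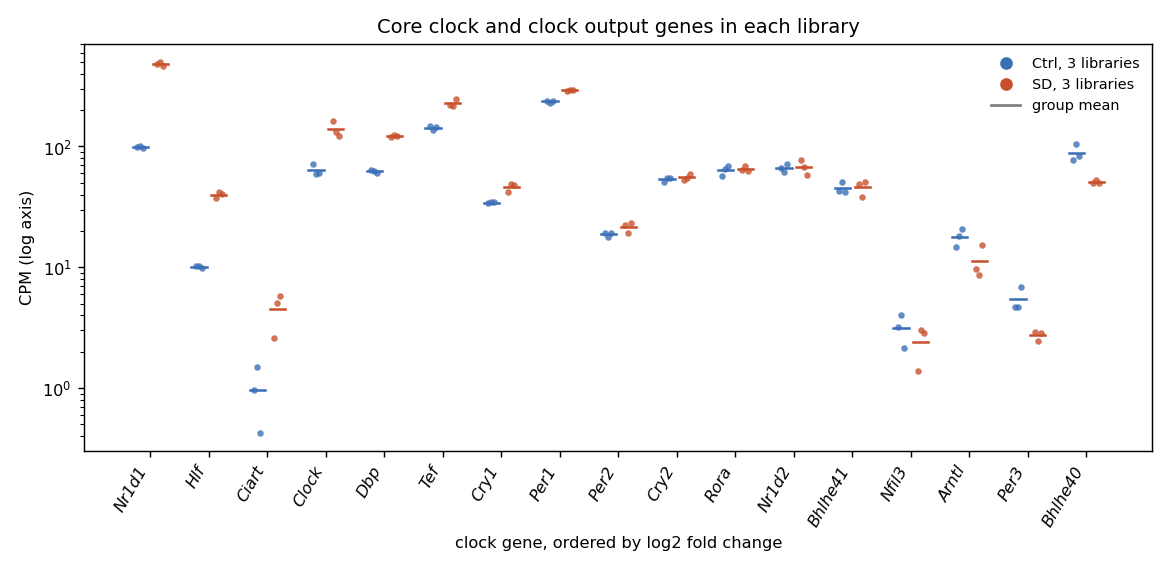
CPM on a log axis for 17 of the 18 tested clock genes, with 1 point per library, lines for group means, Ctrl in blue and SD in orange. Nr1d1 rose from a mean of 99.4 to 479, and Arntl fell from 17.8 to 11.2.

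Of the 18 tested clock list members, 8 rose, 4 fell and 6 did not pass, with the same 8 and 4 when adjusted over the list alone. The list was called higher by camera (adjusted p = 0.049, median log2 fold change 0.12), and the call was lost with an estimated correlation (adjusted p = 0.18 with an estimated correlation). It was also lost without the first 60 genes (adjusted p = 0.10, median 0.051), without SD replicate 3 (adjusted p = 0.061), without a filter, with a filter of 10 reads, with a pseudocount of 0.1 and on TPM. Of this list, the run without the first 60 left out only Clock, which rose, so a weaker upward shift there was set by the exclusion. Leaving out 1 library gave medians of 0.12 to 0.21. Per3 did not pass without Ctrl replicate 3 (adjusted p = 0.089).

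Fatty acid oxidation genes fell into 2 sets that followed their place in the table. Of the 28 tested members, 13 rose and 11 fell, and 4 did not pass. All 13 that rose were among the 60 genes listed first, and 12 of them held SD values that were not whole reads. Decr1, an enzyme for unsaturated fatty acids, was the other. Among the 15 members listed after the first 60 genes, 0 rose, 11 fell and 4 did not pass. Acsl1, which activates long-chain fatty acids, went from 14.88 ± 1.695 to 71.56 ± 12.95 CPM (4.81-fold), Acsl3 from 44.6 ± 5.71 to 99.0 ± 14.2 and Etfdh, which passes electrons to the respiratory chain, from 79.9 ± 3.31 to 165 ± 4.48. All 3 stood in the first 60 and held SD values that are not whole reads. Outside the first 60, Acsl4 (chromosome X, 142317993 to 142390535) fell 3.38-fold from 271 ± 19.3 to 80.1 ± 5.36 (adjusted p = 3.5e-23) and Acsl5 fell 1.76-fold from 73.3 ± 5.04.

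**Figure D2:**
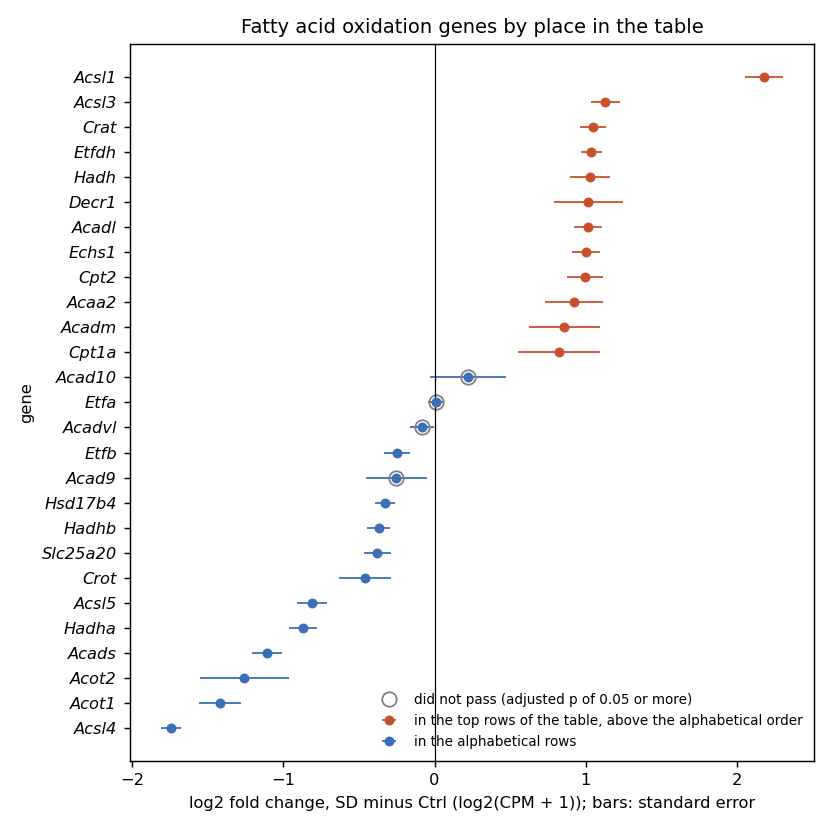
Log2 fold change, SD minus Ctrl on log2(CPM + 1), of 27 of the 28 tested fatty acid oxidation genes; points are estimates, bars standard errors, and grey rings mark genes that did not pass. The 12 genes shown from the top of the table (orange) lie above 0, and among the 15 others (blue) the 11 that passed lie below 0.

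The fatty acid oxidation list was not called by camera (adjusted p = 0.53, median 0.12; adjusted p = 0.55 with an estimated correlation), and adjusting over the list alone gave the same 13 and 11. Leaving out 1 library moved its median to between 0.017 and 0.18. Without the 50 genes holding values that are not whole reads, it was called lower (adjusted p = 0.0038, median -0.37), and likewise without the first 60 (adjusted p = 0.00092, median -0.38). Both runs left out only members that rose, so a downward shift was set by the exclusion and these p-values do not test the list. Of the 60 genes listed first, 59 were tested and all 59 were higher in SD, with folds of 2.01 to 4.81 and 53 of the 60 between 2 and 2.5. Elsewhere 946 of 9945 tested genes (9.5%) had a ratio of mean CPM of at least 2, SD over Ctrl, whether they passed or not. The fold of each gene in the first 60 is therefore given as deposited.

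Lipid synthesis genes were lower in SD. Fasn, the fatty acid synthase, fell 7.15-fold from 176 ± 11.9 to 24.5 ± 2.53 (adjusted p = 1.1e-25). Acly, which supplies cytosolic acetyl-CoA, fell 2.46-fold, Elovl1, an elongase, 2.36-fold and Me1, a source of NADPH, 3.63-fold. Type 2 alveolar cells, in which surfactant lipid is made, had lower markers in the same comparison (median -2.02). Of 18 fatty acid and triglyceride synthesis genes 12 fell, 4 did not pass and 2 rose, Acacb and Dgat2 (camera adjusted p = 0.00021; adjusted p = 0.088 with an estimated correlation). Cholesterol synthesis genes fell in 11 of 15 cases and rose in 0, with 4 not passing (camera adjusted p = 0.0058; adjusted p = 0.13 with an estimated correlation). Hmgcs1, an early enzyme of that pathway, fell 2.10-fold from 94.8 ± 2.67, and Insig1, a sterol-controlled regulator, 2.78-fold from 40.1 ± 4.39. Adjusting over the list alone gave the same counts for both. PPAR targets moved both ways, 4 higher and 4 lower of 11 with 3 not passing (4 and 5 when adjusted over the list alone). Plin2, a lipid droplet coat protein, fell 2.40-fold, and Cd36, 1 of the first 60 genes, was higher. The list was not called (adjusted p = 0.63; adjusted p = 0.67 with an estimated correlation).

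Proliferation genes fell. Top2a, the DNA topoisomerase of dividing cells, went from 27.3 ± 4.21 to 5.54 ± 1.001 (4.93-fold lower, adjusted p = 2.0e-12), and the replication helicase subunits Mcm3 and Mcm2 fell 2.61-fold and 2.68-fold. In the cell cycle list 20 of 27 members fell, 0 rose and 7 did not pass (21 fell when adjusted over the list alone; camera adjusted p = 0.00017; adjusted p = 0.088 with an estimated correlation). In the same comparison alveolar macrophage and type 2 alveolar markers were lower (medians -1.13 and -2.02) and ciliated, endothelial and smooth muscle markers higher (1.64, 0.81 and 1.14). Transcripts downstream of RAS-MAPK signalling moved in both directions, with more falls than rises. Etv5, a transcription factor induced by the pathway, fell 4.90-fold from 244 ± 3.69 and Ccnd1, cyclin D1, 2.93-fold from 159 ± 2.68. Etv5 is also a member of the type 2 alveolar marker list, which fell. Of 17 members 8 fell, 6 did not pass and 3 rose, Spred2, Fosl1 and Etv1, with the same counts adjusted over the list alone and a list call of lower (camera adjusted p = 0.046; adjusted p = 0.18 with an estimated correlation). That call was lost after quantile normalization (adjusted p = 0.057), with a pseudocount of 0.1 (adjusted p = 0.051) and on TPM (adjusted p = 0.081). In the list named for lung adenocarcinoma progression 9 of 13 members fell and 3 did not pass. Among those that fell were Cldn18, a tight junction protein of alveolar cells (4.38-fold), and the keratins Krt7 and Krt8 (1.95-fold and 1.75-fold). The list mixes alveolar genes such as Cldn18 with others, so its direction does not stand for more or less progression. Sox2, a transcription factor of airway epithelium, was the sole riser, from 22.4 ± 0.167 to 114 ± 11.9 (camera adjusted p = 0.0051; adjusted p = 0.13 with an estimated correlation; the same counts adjusted over the list alone).

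Markers of several lung cell types differed between the groups. Counts are of tested members, which were 10 of 17 listed for type 2 cells and 10 of 21 for alveolar macrophages. For club and secretory cells 5 of 13 listed were tested, and for B cells 5 of 18. Type 2 alveolar cell markers fell in 9 of 10 cases. Sftpc, surfactant protein C, went from 4033 ± 266 to 1180 ± 37.6 (adjusted p = 1.0e-30) and Sftpb, surfactant protein B, from 536 ± 35.5 to 88.5 ± 1.77. The tenth member, Cd36, rose and is 1 of the first 60 genes. Alveolar macrophage markers fell in 8 of 10 cases, with Mrc1, the mannose receptor, 8.39-fold lower and Atp6v0d2 6.01-fold lower. The 1 that rose, Fabp1, is again in the first 60, with SD values that are not whole reads, and 1 did not pass. Ciliated airway cell markers rose in 11 of 11 cases, Foxj1, the master regulator of motile cilia, from 61.0 ± 3.24 to 218 ± 13.9 and Tppp3 from 263 ± 5.90 to 1006 ± 10.9. Club and secretory cell markers rose in 5 of 5, led by Aldh1a1 (3.06-fold). Cyp2s1 of that list did not pass without Ctrl replicate 2 (adjusted p = 0.066).

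Endothelial markers rose in 13 of 16 cases, with Ramp2 4.89-fold and the receptor Tie1 2.62-fold higher, while Aplnr fell and 2 did not pass; Tek, 1 of those that rose, is in the first 60 genes and its SD values are not whole reads. Smooth muscle and pericyte markers rose in 12 of 15 cases, including the contractile proteins Tagln (2.75-fold), Acta2 (2.93-fold) and Myh11 (2.74-fold), while Postn and Mylk fell and 1 did not pass. Adjusting over the list alone left the counts of these 6 lists as they were. Camera called type 2 (adjusted p = 2.0e-09), alveolar macrophage (0.0014), ciliated (1.1e-07), club (0.0079), endothelial (2.6e-06) and smooth muscle markers (1.0e-05). With an estimated correlation none was called. The adjusted p with an estimated correlation was 0.074, 0.14, 0.074, 0.17, 0.13 and 0.088 in that order. For type 2, ciliated and smooth muscle markers the estimated correlation (-0.00424, -0.0409 and -0.0511) lay below the preset. The loss of those calls therefore did not come from correlation between genes. Type 1 alveolar markers rose in 7, fell in 5 and did not pass in 1 of 13 cases (7 and 6 when adjusted over the list alone). Aqp5 fell 2.47-fold and Hopx rose 1.82-fold. Cav1, which also rose, is in the first 60 with SD values that are not whole reads. The list was not called (adjusted p = 0.63; adjusted p = 0.67 with an estimated correlation). B cell markers rose in 4 of 5 cases, Pax5 from 3.82 ± 0.760 to 22.0 ± 1.54, with 1 not passing and the same count adjusted over the list alone (camera adjusted p = 0.043; adjusted p = 0.18 with an estimated correlation). The B cell call was lost with limma-voom (adjusted p = 0.12) and DESeq2 (adjusted p = 0.095).

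**Figure D3:**
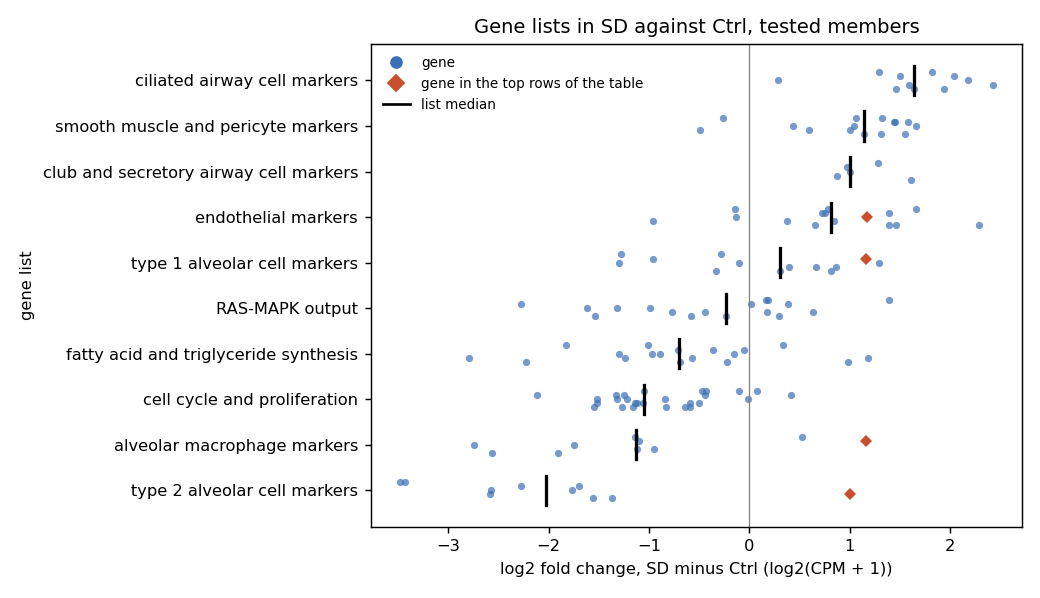
Log2 fold change, SD minus Ctrl on log2(CPM + 1), of the tested members of 10 gene lists. Each point is a gene, orange diamonds are genes from the first 60 of the table and black bars are list medians, from -2.02 for type 2 alveolar markers to 1.64 for ciliated cell markers.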

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

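TMM scaling and the runs without the 50 genes holding values that are not whole reads or without the first 60 genes were chosen after the results were seen. The count of changed genes stayed within 1.5 times 5667 in all 23 alternative fits, from 5057 without Ctrl replicate 3 to 5690 with sample weights, and was 5619 and 5608 without the 50 and the 60 genes. Requiring 2-fold left 1434 genes, 776 higher and 658 lower, by its construction. The 17 called lists became 0 with an estimated correlation, where camera also had fewer degrees of freedom. With fry, which does not compare a list with other genes, 35 were called, and elsewhere 14 to 18. Replicate numbers did not pair the libraries (same-numbered deviations correlated at -0.007, -0.019 and 0.012). With the replicate block 5603 genes changed, 2785 higher and 2818 lower, and 17 lists were called. Among 140 genes followed, 13 gene and setting pairs lost their call and 8 changed sign, the latter all leave-one-out runs of clock genes near 0. Over the leave-one-out runs Bhlhe41 ran from -0.05548 to 0.1463, Rora from -0.04548 to 0.08607 and Nr1d2 from -0.07466 to 0.1238, and the cause was not tested. Of the 18 lists followed, fatty acid oxidation turned from 0.12 to -0.37 without the 50 genes (-0.3744) and to -0.38 without the 60 (-0.3785), because the members that rose were left out. There were 19 list and setting pairs that lost their call, among the clock, heat shock, RAS-MAPK, NRF2 and B cell lists. Of these, the NRF2 runs without the 50 or the 60 genes and the clock run without the 60 left out only members that rose. The cause of the others was not tested. At 6511192 to 7417095 reads, genes under about 1 CPM rest on fewer than 10 reads per library.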

Other observations

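The tests of the 3 patterns below, and the runs without the 50 genes whose values are not whole reads, were chosen after the results were seen, while the list tests and the splits were planned. In glycolysis 13 of 19 members fell, with Ldha, lactate dehydrogenase A, from 160 ± 6.51 to 49.9 ± 6.74 CPM and Gapdh from 1513 ± 11.9 to 936 ± 11.3, while Slc2a1, Pfkfb3 and Slc16a3 rose and 3 did not pass (camera adjusted p = 0.0079; adjusted p = 0.33 with an estimated correlation). In the TCA cycle 12 of 19 fell, Ogdh 2.04-fold and Cs, citrate synthase, 1.72-fold, while Sdhc and Sdhb rose and 5 did not pass (adjusted p = 0.011; adjusted p = 0.18 with an estimated correlation). Nuclear genes of oxidative phosphorylation were lower in 8 and higher in 2 of 21 cases, 11 did not pass, and that list was not called (adjusted p = 0.079; adjusted p = 0.20 with an estimated correlation). Adjusting over the list alone left the counts of these lists as they were. In the same comparison type 2 alveolar markers had a median of -2.02, alveolar macrophage markers of -1.13 and ciliated cell markers of 1.64.

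Heat shock genes rose in 13 of 20 cases and fell in 5, with 2 not passing (13 and 6 when adjusted over the list alone). Cryab, a small heat shock protein, rose 1.50-fold from 741 ± 26.5, while Hspa8, the constitutive chaperone, fell 1.29-fold from 3403 ± 65.4. The list was called (adjusted p = 0.046; adjusted p = 0.26 with an estimated correlation), and the call was lost in 6 alternatives, without SD replicate 1 among them (adjusted p = 0.058). NRF2 and oxidative stress genes rose in 12 of 22 cases, fell in 4 and did not pass in 6, the same when adjusted over the list alone. Gpx2, a glutathione peroxidase, rose 3.93-fold from 38.6 ± 6.12 and Gclm, of glutathione synthesis, 2.41-fold from 135 ± 9.58. Its call (adjusted p = 0.019; adjusted p = 0.17 with an estimated correlation) was lost without the 50 genes (adjusted p = 0.17), 3 of which are members, Sod1 among them. The 3 members left out were all higher in SD. The heat shock and NRF2 rises stood beside higher club, ciliated, endothelial and smooth muscle markers (medians 1.005, 1.639, 0.809 and 1.137) and the lower type 2 and macrophage markers given above. Glucocorticoid-responsive genes moved both ways, 7 higher, 5 lower and 2 not passing, also when adjusted over the list alone. Klf9 was 1.74-fold higher and Errfi1 2.62-fold lower, and the list was not called (adjusted p = 0.12; adjusted p = 0.34 with an estimated correlation). The unfolded protein response list, with 8 higher, 7 lower and 8 not passing of 23 (9 and 9 when adjusted over the list alone), was not called (adjusted p = 0.81; adjusted p = 0.88 with an estimated correlation). Neither was hypoxia response, with 4 higher, 8 lower and 5 not passing of 17 (4 and 10 when adjusted over the list alone; adjusted p = 0.46; adjusted p = 0.65 with an estimated correlation). Ddx3y, of the Y chromosome, lay between 91.0 and 112 CPM in the 6 libraries.

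With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split was the 1 with 5667 changed genes, and the highest of the others had 0. It was also the 1 with 17 called lists, and the highest of the others had 9. All other splits mix Ctrl and SD libraries, so the difference between the groups enters their residual spread. Few or no calls there were thus set by the design, and these counts do not show what chance would give.

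The first pattern is the values that are not whole reads, 121 of 124 in SD columns and all in genes among the 60 listed first. In 50 of the 60 genes listed first (83.3%), the recovered SD reads of all 3 libraries became whole when divided by 1 common factor between 1.1 and 3.0 in steps of 0.1, against 23.3% for the Ctrl reads of the same genes and 16.5% for the SD reads of the rest of the table. For Acsl1 the SD reads were 556.4, 483.6 and 400.4, and the factors found within that range ran from 1.3 to 2.6. Factors above 3.0 were not searched. Counting shared reads as fractions would also touch Ctrl, which held 2.4% of these values, and a scaling of whole libraries would leave few whole reads in SD, where 99.6% of values were whole. A candidate explanation is 1 multiplier per gene applied to the SD values after counting, which says nothing of who applied it or why. A common factor was found for 42 of the genes whose values are not whole reads and 8 others. Dividing these by the smallest such factor would give a median fold of 1.63. The largest factor within the search would give 1.45, with 10 below 1. A factor above 3.0 would give lower folds still, so the folds without a multiplier stay open.

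The second pattern is the lower type 2 alveolar markers with higher airway, endothelial and smooth muscle markers in SD. A lower share of type 2-like cells alone would raise the markers of other types alike. Alveolar macrophage markers outside the first 60 genes, 9 tested of 21 listed, had a median of -1.137 (95% bootstrap interval -2.561 to -0.947). Interstitial macrophage and monocyte markers, 5 higher, 1 lower and 3 not passing of 9, had a median of 0.492. T cell markers, 5 higher, 0 lower and 4 not passing of 9, had a median of 0.451. Camera called neither of these 2 lists. The intervals in this paragraph resample genes that may move together, so they do not measure the spread between samples. Samples with more airway and vessel wall and less alveolar tissue may also give the pattern. Type 1 markers outside the first 60 genes, with a median of 0.101 (-0.649 to 0.737), left that open. Over all 13 tested type 1 markers the median was 0.309. A lower share of tumour tissue is likewise possible, and the RAS-MAPK output genes, with a median of -0.237 (-0.989 to 0.186), did not decide it. A change within the cells of the SD group stays open too, untested, since group and tissue make-up cannot be told apart here.

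The third pattern is how little the libraries of a group differed, with log2 correlations of 0.987 to 0.991 within groups. A library sequenced again would give a median chi-square per gene near 0.455 between its runs, and the lowest of the 6 pairs was 1.027. Separate libraries of 1 RNA pool per group may show so low a biological coefficient of variation, 0.0693 in the edgeR fit, but the labels give no measure of preparation noise to set it against. Whether the libraries stand for separate animals therefore stays open.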
